A study of Mus musculus with 12 samples.

How the data were processed

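Kidney poly(A) RNA was measured in 12 libraries by paired-end sequencing on an Illumina platform, per the labels' protocols, after fragmentation and random-primed cDNA synthesis. Each of the 4 groups held 3 libraries. The values analysed are FPKM, which scales fragments for gene length and sequencing depth, as the authors deposited them, 1 value per gene and library. HTSeq and the genome build GRCm39 are named in the submitters' processing notes, without versions, and the aligner, the annotation and the strand setting are not given in the sources used here. Exon lengths from GENCODE M21 (GRCm38), which served as a reference here, turned the deposited FPKM into whole fragments for 21392 genes (97.9% of those with a length, tolerance 0.05 of a fragment), so the values were treated as made with gene models of that kind. Coordinates are therefore given in GRCm38, and the difference from the build named in the notes stays open. No value column was left unused. How the mice were made to have more or less GABP is not given in the sources used here.

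The table held 21899 genes, of which 21795 had a symbol and 21846 an M21 exon length. Fragments per gene were recovered by dividing each FPKM by the value of 1 fragment for that gene and library, and 97.7% to 98.1% of the values above 0 in a library came out whole. Total fragments per library were 6.78 to 9.70 M (M, 1e6), and 12539 of the 12897 genes tested had whole fragments throughout. PCR duplicates could not be told apart from separate molecules, so counting intervals (95%, exact) and the floor of 3 fragments cover counting error only. Replicate pairs differed by 4.7 to 45.1 times the counting noise (chi-square per degree of freedom), and no library was a copy of another.

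The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), for genes with FPKM of at least 0.3 in at least 3 libraries, with 1 mean per group, all 12 libraries in 1 fit, no block, moderated variances with a trend, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Comparisons were db/db-veh against db/m-veh, db/m-GABP-OE against db/m-veh, db/db-GABP-KD against db/db-veh, and the GABP-OE effect minus the GABP-KD effect. Gabpa, Gabpb1, Gabpb2 and Gli1 were also compared by exact permutation of group means. Gene lists, 34 in number, were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists within a comparison) when at least 3 members were measured, which left 32. Members called over all genes were counted, and again with p adjusted over the list alone. The lists were also tested as deposited with fry, which asks whether members change at all and so takes in any all-gene shift. Its p, adjusted as for camera, is given for members moving in 1 direction. Where that called no list, the result for members moving either way is given too. Adrenal and skeletal muscle genes had too few measured members to test.

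The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule Gabpa, Gabpb1, Gabpb2 and Gli1 are always named. So are the 10 largest rises and falls among called genes with mean FPKM of at least 1 in the higher group and no overlap of libraries, leaving out predicted and sex-linked genes. From each list with a called test or member up to 4 members are named, those with the smallest adjusted p or, where no member was called, those with the largest fold change. A few members that the rule selects are not used here. In the difference of effects the condition on overlap has no meaning and was not applied. Genes in more than 1 comparison are named by the size of the smaller change.

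Alternatives were other pseudocounts (0.1 and 1), no filter, a filter of FPKM 1, median of ratios scaling (from 5884 genes above FPKM 1 in every library), an equal FPKM sum (TPM), quantile normalization, no variance trend, library weights, the replicate number as a block, a minimum log2 fold change of 1, fits of 2 groups, camera with an estimated correlation, and each library left out. voom from limma on the recovered fragments, and the leave-out of db/db-GABP-KD 1 in comparisons without it, were added after seeing the data. The fit was tested on simulated data for the GABP-OE comparison over 12088 genes, where it called 7.5% of genes changed 2-fold, 70.1% of those changed 4-fold and 87.9% of those changed 8-fold, with 6 false calls. Changes were planted in genes with more fragments only. The simulated libraries held no all-gene shift, unlike the data (size factors 0.53 to 1.71), and no shared animals. These rates may therefore not hold for the data. Mean log2 levels of gene sets per library were compared with the spread pooled over the 4 groups, after the values were seen. Shared controls were simulated 100 times. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.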

Results

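Messenger RNA was sequenced from mouse kidney in 4 groups of 3 libraries each. The db/m-veh and db/db-veh groups received vehicle. db/db mice lack a working leptin receptor and become obese and diabetic, and db/m mice are their lean, heterozygous controls. In db/m-GABP-OE mice GABP was to be raised, and in db/db-GABP-KD mice it was to be lowered. GABP is a transcription factor made of an alpha subunit, which binds DNA, and a beta subunit, and it is known to bind promoters of many genes for mitochondrial proteins. Kidney tissues of 6 mice per group were used, with 3 tissues mixed for each extraction. Filling 3 separate pools takes 9 portions, more than the 6 mice, so pools may share animals if each library is its own pool. With shared animals the p-values, which treat libraries as independent, may be too small. Whether the 3 libraries of a group are separate pools or repeats from the same pool is not given in the sources used here, and with repeats n = 3 would not count independent samples.

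The values correspond to 6.78 to 9.70 M fragments per library (M, 1e6). The 13 mitochondrially encoded genes took 47.9% (db/db-GABP-KD 1) to 86.0% (db/db-veh 2) of these fragments. Their share was 71.8% ± 5.25 (SD, n = 3) in db/m-veh, 78.8% ± 6.21 in db/db-veh, 60.9% ± 2.91 in db/m-GABP-OE and 65.8% ± 15.5 in db/db-GABP-KD. The exact permutation p for the share was 0.3 between the vehicle groups, 0.1 for GABP-OE and 0.3 for GABP-KD, where 0.1 is the smallest two-sided p that 3 against 3 libraries allow. Nuclear genes were left with 1.08 to 4.39 M fragments. Because FPKM divides by all fragments, nuclear genes as a whole shifted between groups. The median log2 fold change of the 12897 genes tested was -0.24 for db/db-veh against db/m-veh, 0.38 for GABP-OE and 0.42 for GABP-KD. After scaling by median of ratios these medians were 0.01, 0.04 and 0.00. Library db/db-GABP-KD 1 stood apart from the other 11 libraries, with a mean correlation of 0.87 to the others of its group and a loading of 0.768 on the second principal component (21.3% of the variance). On the first component (42.7%) the largest loading was that of db/db-veh 2, at 0.621. After median of ratios db/db-GABP-KD 1 had the largest loading on the first component (0.638), with db/db-veh 2 at 0.128.

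**Figure D1:**
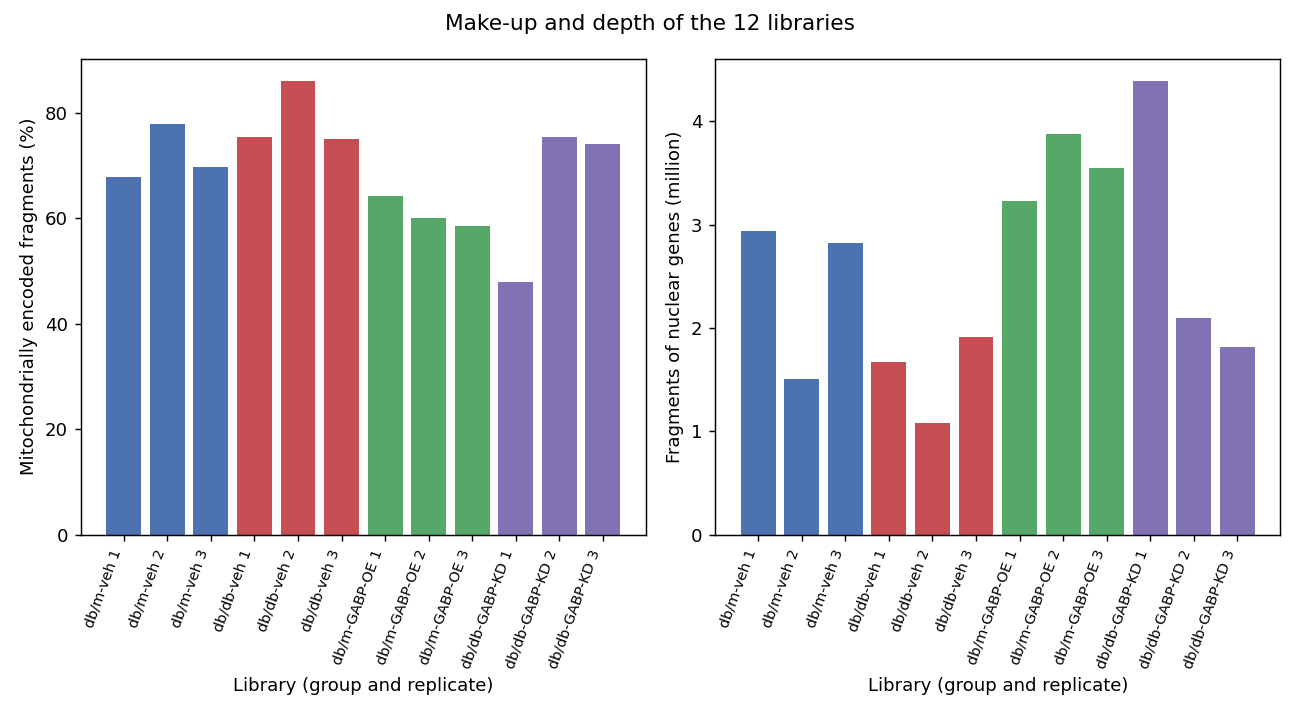
Percent of fragments from the mitochondrially encoded genes (left axis panel) and fragments of nuclear genes in M (right panel), 1 bar per library, coloured by group. The share lay between 47.9% in db/db-GABP-KD 1 and 86.0% in db/db-veh 2, and nuclear fragments between 1.08 and 4.39 M.

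Levels of the targeted factor were examined first, as a check of the labels. Gabpa (ENSMUSG00000008976, GRCm38 chromosome 16, 84834925 to 84863779, plus strand, exons of the whole gene counted) encodes the DNA-binding subunit. It stood at 2.22 ± 0.388 FPKM (SD, n = 3) in db/m-veh, 2.00 ± 0.324 in db/db-veh, 3.50 ± 0.183 in db/m-GABP-OE and 4.23 ± 2.10 in db/db-GABP-KD. Gabpa was therefore not lower in the libraries labelled GABP-KD than in db/db-veh. The log2 fold change there was 0.84 (SE 0.33, limma adjusted p = 0.34), or 0.31 with a 95% interval of -0.24 to 0.87 after median of ratios. As deposited all 3 libraries lay above all 3 of db/db-veh, with a ratio of means of 2.12 (exact permutation p = 0.1). After median of ratios it was 1.24 (exact permutation p = 0.4). With GABP-OE the log2 fold change of Gabpa was 0.57 (SE 0.33, limma adjusted p = 0.43), all 3 libraries lay above all 3 of db/m-veh, and the ratio of means was 1.58 as deposited (exact permutation p = 0.1) and 1.16 after median of ratios (exact permutation p = 0.4). A rise of Gabpa in the libraries labelled GABP-OE was therefore not established by these tests. Between the vehicle groups the log2 fold change of Gabpa was -0.12 as deposited and 0.20 after median of ratios (limma adjusted p = 0.93 and 0.81). Gabpb1 (ENSMUSG00000027361, chromosome 2, 126627442 to 126676337, minus strand) and Gabpb2 (ENSMUSG00000038766, chromosome 3, 95181766 to 95217916, minus strand) encode beta subunits. Gabpb1 was at 1.08 ± 0.217, 1.16 ± 0.466, 1.92 ± 0.343 and 2.14 ± 1.84 FPKM in the same group order, and Gabpb2 at 0.481 ± 0.196, 0.396 ± 0.245, 0.747 ± 0.079 and 0.695 ± 0.083. Neither passed the test in any comparison.

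Gli1 encodes a zinc finger transcription factor that carries Hedgehog signals, and the series title names it as a target of GABP. The gene (ENSMUSG00000025407) lies on GRCm38 chromosome 10, 127329882 to 127341974, minus strand. Its level was 0.160 ± 0.090 FPKM (SD, n = 3) in db/m-veh, 0.492 ± 0.41 in db/db-veh, 1.37 ± 0.90 in db/m-GABP-OE and 0.044 ± 0.036 in db/db-GABP-KD. These levels rest on 20, 53, 184 and 5 fragments per group. Gli1 rose with GABP-OE by 1.40 on the log2(FPKM + 0.5) scale (SE 0.35, limma adjusted p = 0.049), with 3 of 3 libraries above every db/m-veh library and a fragment ratio of 8.52 (95% interval 5.36 to 14.3). Library db/m-GABP-OE 3 held 102 of the 184 fragments, against 29 in db/m-GABP-OE 1 and 53 in db/m-GABP-OE 2. The exact permutation p of the difference in means was 0.1. That call was lost after median of ratios (log2 fold change 1.12, adjusted p = 0.3, within a range over the alternatives of 0.00052 to 0.32), and also without db/m-veh 1 (0.067), db/m-veh 2 (0.13), db/m-veh 3 (0.22), db/m-GABP-OE 2 (0.13) or db/m-GABP-OE 3 (0.2). It was lost too with no filter (0.084), pseudocount 0.1 (0.12), no variance trend (0.099) and quantile normalization (0.32), and stayed in 6 of 16 alternatives. Between the libraries labelled GABP-KD and db/db-veh the fragment ratio was 0.087 (95% interval 0.027 to 0.216), with log2 fold change -0.76 (SE 0.35, limma adjusted p = 0.34) and exact permutation p = 0.2, since db/db-veh 2 held a lone Gli1 fragment against 27 and 25 in the other db/db-veh libraries. For db/db-veh against db/m-veh the ratio was 3.02 (95% interval 1.78 to 5.34, limma adjusted p = 0.63). Intervals of fragment ratios cover counting error only, not the spread between animals. The difference of the GABP-OE and GABP-KD effects on Gli1 was 2.17 (SE 0.49, limma adjusted p = 0.15). Of 9 measured Hedgehog pathway genes, Gli1 was called alone with GABP-OE, 3 were higher when adjusted over the list alone (0 after median of ratios), and the list did not differ from other genes (camera adjusted p = 0.44).

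**Figure D2:**
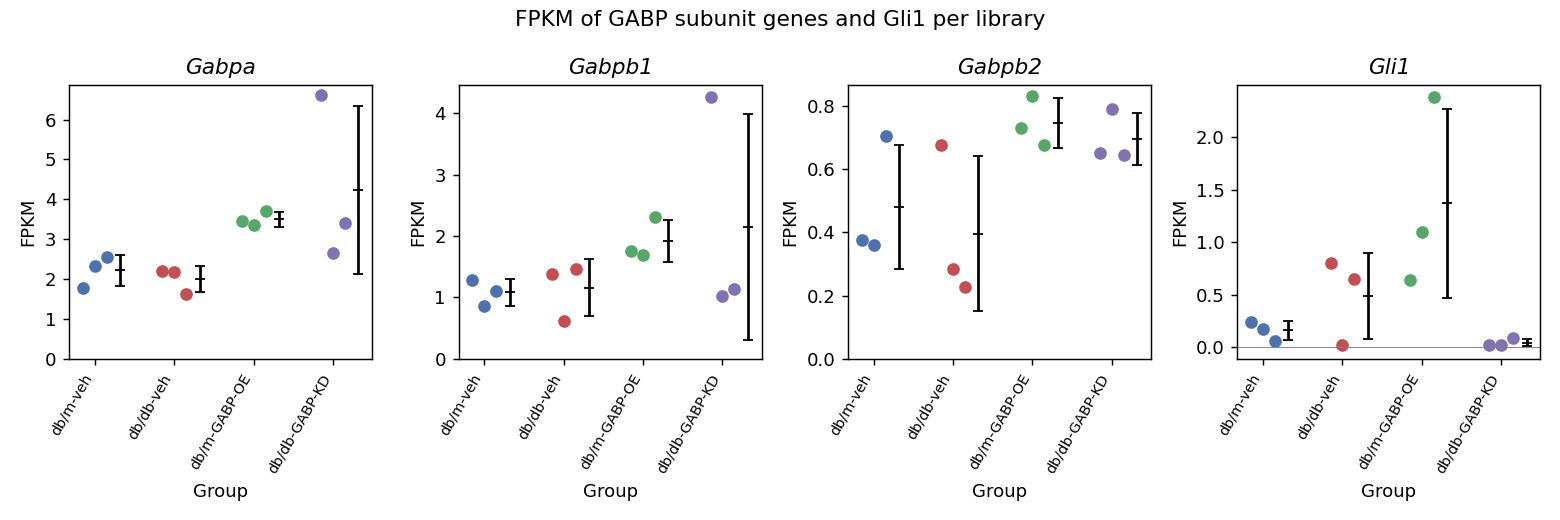
FPKM of Gabpa, Gabpb1, Gabpb2 and Gli1 in each library (points, 3 per group) with the group mean and SD (black). Gabpa in db/db-GABP-KD averages 4.23 FPKM against 2.00 in db/db-veh, and Gli1 averages 1.37 in db/m-GABP-OE against 0.160 in db/m-veh.

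Diabetic and control kidneys under vehicle differed in a small set of genes. Slc22a7, a proximal tubule carrier of organic anions, fell from 13.9 ± 10.7 FPKM (SD, n = 3) in db/m-veh to 0.111 ± 0.0858 in db/db-veh (log2 fold change -4.32, SE 0.45, limma adjusted p = 0.00031). Kap, an androgen-regulated kidney transcript, fell from 8170 ± 6230 to 678 ± 286 FPKM (log2 fold change -3.38, SE 0.57, limma adjusted p = 0.024). The steroid-metabolizing genes Akr1c18, Cyp7b1 and Hsd3b4 fell as well, by 3.28, 2.83 and 1.89 on the log2 scale. Akr1c18 had 1 fragment in db/db-veh against 166, a ratio of 0.00687 (95% counting interval 0.000173 to 0.0388). The glucuronosyltransferase gene Ugt1a2 rose from 0.0161 ± 0.028 to 8.97 ± 0.552 FPKM, that is from 1 to 441 fragments (ratio 503, 95% counting interval 89.9 to 19900, log2 fold change 4.20, limma adjusted p = 0.00031). Ugt1a10 rose by 2.46, and so did Gc, which encodes the vitamin D-binding protein, from 3.93 ± 1.47 to 23.0 ± 2.61 FPKM.

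Histone gene Hist1h4h and the class II antigen-loading gene H2-DMb1 fell by 2.72 and 1.84. Ugt1a2 and Ugt1a10 share exons with each other, and Hist1h4h, H2-DMb1 and Hsd3b4 have near-identical relatives, so their values are uncertain. In all, limma called 12 genes (4 higher, 8 lower, 1489 at an unadjusted p under 0.05), and all 12 were among the 22 called after median of ratios (7 higher, 15 lower). The other called genes, 2210011C24Rik (lower) and Gm6614 (higher), fell outside the naming rule and are named after their values were seen. The count depended on single libraries, being 3 without db/m-veh 1, 22 without db/m-veh 2, 4 without db/m-veh 3, 2 without db/db-veh 1, 3 without db/db-veh 2 and 48 without db/db-GABP-KD 1, which shares the estimate of spread. Slc22a7 and Ugt1a2 stayed called in each of the leave-outs of the vehicle libraries, whereas the other 8 named genes lost the call without at least 1 of these 6 libraries. voom on the recovered fragments called 3 genes, and 1 with median of ratios sizes.

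Groups of nephron genes moved apart between the vehicle groups, measured against all other genes with camera. All 7 distal convoluted tubule markers lay above the all-gene median (list median 0.74 above it, 3 higher over the list alone after median of ratios, camera adjusted p = 1.08e-05, adjusted p = 0.57 with an estimated correlation), with the calcium-binding protein gene Calb1 at 14.96 ± 3.41 FPKM against 8.01 ± 3.85 and the magnesium channel gene Trpm6 at 2.01 ± 0.418 against 1.00 ± 1.12, Pvalb at 11.5 ± 1.28 against 7.02 ± 0.346 and Klhl3 at 3.64 ± 1.28 against 2.67 ± 1.92. All 13 collecting duct markers lay below it (camera adjusted p = 0.000889, adjusted p = 0.57 with an estimated correlation), and 4 were lower when adjusted over the list alone (3 after median of ratios). Among them, Fxyd4 was at 1.72 ± 0.453 against 7.85 ± 3.15 FPKM and the proton pump gene Atp6v0d2 at 2.66 ± 0.856 against 9.10 ± 3.59, beside Foxi1 at 2.96 ± 0.368 against 7.50 ± 2.11 and Atp6v1g3 at 5.53 ± 0.899 against 14.8 ± 9.40. Of 15 proximal tubule markers, Slc22a7 was called alone, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.233). Among 17 cytochrome P450 and drug metabolism genes Cyp7b1 was called, 1 was higher and 3 were lower when adjusted over the list alone (2 and 3 after median of ratios), and the list was not called (camera adjusted p = 0.326). Endothelial markers were low as a list (camera adjusted p = 0.0149, adjusted p = 0.77 with an estimated correlation), with Ehd3 at 4.11 ± 0.840 against 8.56 ± 4.59 FPKM and Tie1 at 3.70 ± 1.62 against 6.73 ± 2.14, Plvap at 32.3 ± 11.3 against 53.7 ± 7.34 and Egfl7 at 3.95 ± 2.38 against 5.83 ± 1.495.

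Metabolic, stress and clock genes differed between the vehicle groups as lists by camera, with no member passing over all genes. Of 17 circadian clock genes 13 lay above the all-gene median (camera adjusted p = 1.08e-05, adjusted p = 0.57 with an estimated correlation), and 1 was higher when adjusted over the list alone (3 higher and 1 lower after median of ratios). The clock-controlled genes Ciart and Dbp stood at 5.38 ± 3.38 against 0.338 ± 0.252 FPKM and at 6.01 ± 3.68 against 1.81 ± 0.719, Cry2 at 1.85 ± 1.30 against 0.513 ± 0.0118 and Npas2 at 0.194 ± 0.175 against 1.09 ± 0.479. The clock list was fixed as a check of sampling time. A difference in sampling time between the groups was not tested and cannot be told apart here from one of strain. Lower lists were the nuclear-encoded respiratory chain (22 of 27 at or below the all-gene median, camera adjusted p = 0.00439, adjusted p = 0.8 with an estimated correlation), the NFE2L2 antioxidant response (0.00435 and 0.8, with 2 genes lower over the list alone after median of ratios) and the unfolded protein response (0.00439 and 0.57, with 4 genes lower when adjusted over the list alone and 1 after median of ratios). The cytochrome oxidase subunit genes Cox6a1 and Cox5b had means of 69.3 ± 52.7 against 265 ± 147 and 27.0 ± 24.3 against 69.2 ± 20.8 FPKM, Cox8a 79.5 ± 54.9 against 191 ± 54.99 and Cox6b1 59.1 ± 38.4 against 120 ± 21.4. Heme oxygenase gene Hmox1 had 4.12 ± 4.52 against 14.0 ± 7.06, Sod1 12.3 ± 4.51 against 31.4 ± 7.74, the chaperone genes Sdf2l1 0.889 ± 0.765 against 5.41 ± 1.36 and Calr 41.0 ± 6.70 against 102 ± 38.1. Gclm had 7.01 ± 1.95 against 17.4 ± 1.34, Srxn1 4.82 ± 1.35 against 12.4 ± 4.77, Pdia4 8.06 ± 1.63 against 19.1 ± 5.54 and Asns 0.244 ± 0.119 against 1.19 ± 0.700. Lipid and cholesterol synthesis was lower with camera adjusted p = 0.0385 (adjusted p = 0.77 with an estimated correlation, 1 gene lower when adjusted over the list alone and 0 after median of ratios), with Hmgcs1 at 6.88 ± 1.54 against 24.5 ± 16.1 and Scd2 at 1.76 ± 0.45 against 4.87 ± 1.88, Cyp51 at 1.09 ± 0.769 against 2.96 ± 1.47 and Idi1 at 0.616 ± 0.437 against 1.34 ± 0.618. Mitochondrially encoded genes lay higher relative to other genes (camera adjusted p = 0.021, adjusted p = 0.8 with an estimated correlation), mt-Nd5 being at 43010 ± 3987 against 31640 ± 4944 FPKM and mt-Nd4l at 25.7 ± 7.83 against 35.5 ± 7.24, mt-Co1 at 207900 ± 16850 against 169200 ± 20070 and mt-Atp8 at 2.08 ± 2.17 against 3.23 ± 4.68. That list is not independent of the mitochondrial share of fragments, which had an exact permutation p of 0.3.

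Markers of blood and fat differed beside these groups. Of 8 red blood cell genes 1 lay above the all-gene median (camera adjusted p = 0.00606, adjusted p = 0.75 with an estimated correlation, 1 lower when adjusted over the list alone and 0 after median of ratios). Hba-a1 was at 143 ± 63.2 against 511 ± 207 FPKM and Hbb-bs at 89.6 ± 41.6 against 301 ± 125, Hbb-bt at 19.6 ± 9.32 against 57.8 ± 18.1 and Hba-a2 at 9.63 ± 4.12 against 29.9 ± 17.6, all from near-identical gene copies. Adipose tissue genes were higher (camera adjusted p = 0.00268, adjusted p = 0.57 with an estimated correlation, 1 higher when adjusted over the list alone, as after median of ratios). Adipoq, the fat cell hormone adiponectin, had 34 fragments against none, and Cidec had 25 against 1 (ratio 28.5, 95% counting interval 4.67 to 1170). For Adipoq the counting bound was 12.9-fold against a floor of 3 fragments over the group. These counts are pooled over the libraries of a group and do not cover the spread between them. Log2 fold changes ran from 0.71 to 2.98 (Adipoq) and 0.58 to 2.01 (Cidec) over 16 alternatives, and 0 of these called either gene. Cfd was at 3.87 ± 6.21 against 0.502 ± 0.349 FPKM, and Ucp1 at 0 against 0.156 ± 0.215. Inflammatory mediators were higher (camera adjusted p = 0.0204, adjusted p = 0.57 with an estimated correlation). Cxcl1 was at 3.36 ± 4.91 against 0.404 ± 0.350 FPKM and Cxcl2 at 69 pooled fragments against 1 (ratio 78.7, 95% counting interval 13.7 to 3150). The log2 fold change of Cxcl2 ran from 0.44 to 2.37 over 17 alternatives, of which 1 called it. Il1b was at 1.29 ± 1.43 against 0.466 ± 0.454 FPKM and Ccl5 at 0.328 ± 0.340 against 0.767 ± 0.468. Median of ratios ended 5 of the 12 list calls, those of endothelial (adjusted p = 0.0597), inflammatory (0.195), lipid synthesis (0.0675), mitochondrially encoded (0.0663) and adipose genes (0.051). With an estimated correlation none of the 12 held. Lipid synthesis lost its call without db/m-veh 1, db/m-veh 2, db/db-veh 2 or db/db-veh 3, mitochondrially encoded genes without db/m-veh 1, db/m-veh 3 or db/db-veh 2, and inflammatory mediators without db/db-veh 2 or db/db-veh 3. Respiratory chain (camera adjusted p = 0.176) and red blood cell genes (0.174) lost it without db/m-veh 2, unfolded protein response (0.0505) and adipose genes (0.0784) without db/db-veh 1, and endothelial markers (0.108) without db/db-veh 2. Of the 12, 8 stayed called without db/db-veh 2, 9 without db/m-veh 2, 10 without db/m-veh 1, db/db-veh 1 or db/db-veh 3 and 11 without db/m-veh 3. By direction fry called no list between the vehicle groups (lowest adjusted p = 0.201). With members free to move either way fry called proximal tubule (0.0227), collecting duct (0.0227), unfolded protein response (0.0187) and drug metabolism genes (0.0187).

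Kidneys of db/m-GABP-OE mice carried far more transcripts of antigen-presenting and other immune cell genes than those of db/m-veh mice. The class II genes H2-Eb1, H2-Aa and H2-Ab1 rose from 11.1 ± 4.24, 7.45 ± 1.87 and 10.1 ± 4.13 FPKM (SD, n = 3) to 122 ± 37.7, 67.1 ± 21.4 and 78.6 ± 28.9, with log2 fold changes of 3.42, 3.06 and 2.89 (limma adjusted p = 0.00061, 0.0024 and 0.013). Jchain, which joins immunoglobulin units in plasma cells, rose from 2.56 ± 2.38 to 45.0 ± 14.2 FPKM (log2 fold change 4.12, SE 0.67, limma adjusted p = 0.0053). Ccl8, a chemokine gene, went from 1 to 137 fragments (ratio 127, 95% counting interval 22.4 to 5050, log2 fold change 4.05, SE 0.37, limma adjusted p = 3.8e-05). Retnla, a marker of alternatively activated macrophages, went from no fragment to 87, at least 26.9-fold higher (log2 fold change 3.39, limma adjusted p = 3.8e-05).

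Igfbp2, an insulin-like growth factor binding protein gene, rose by 3.31 on the log2 scale, Cfd (complement factor D, made by fat cells) by 3.42, the microfibril gene Mfap4 by 3.03 and Mettl7a2 by 3.20. Tm4sf5 fell to 3 fragments from 130 (ratio 0.0214, 95% counting interval 0.00435 to 0.0638, log2 fold change -3.07, SE 0.41, limma adjusted p = 0.0013). Tpm3-rs7, a relative of the tropomyosin gene Tpm3 with shared sequence and therefore uncertain, fell from 9.34 ± 4.44 to 0.568 ± 0.166 FPKM (log2 fold change -3.08, limma adjusted p = 0.0026). Pianp, Fam25c and Tff1 fell by 2.08, 1.92 and 1.66. For Tff1, 2 fragments stood against 25 (ratio 0.0741, 95% counting interval 0.0085 to 0.297). In all, limma called 245 genes, 238 higher and 7 lower (97.1% higher, 1941 at an unadjusted p under 0.05). After median of ratios, which removes the all-gene shift of 0.38, it called 27 of them, 21 higher and 6 lower (77.8% higher), and of the 15 genes just named Jchain, Cfd, Mfap4 and Tff1 were no longer called. voom on the recovered fragments called 7, and 3 with median of ratios sizes. Without db/m-veh 2, db/m-veh 3, db/m-GABP-OE 2 or db/m-GABP-OE 3 the count was 78, 39, 41 and 75, and without db/db-GABP-KD 1 it was 559. Of the 37 called genes named for this comparison, 19, 12, 12 and 16 kept the call in the first 4 of these leave-outs, 29 without db/m-veh 1 and 30 without db/m-GABP-OE 1.

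**Figure D3:**
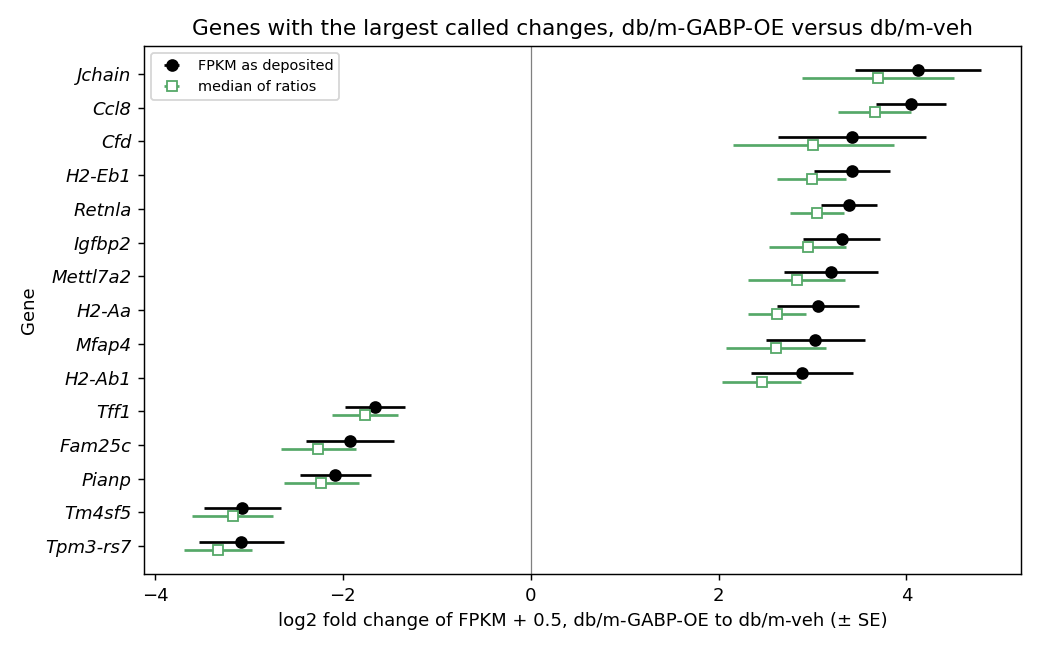
Log2 fold change of FPKM + 0.5 with standard error for the genes with the largest called changes between db/m-GABP-OE and db/m-veh, as deposited (black circles) and after median of ratios (open squares). Jchain lies at 4.12 as deposited, Ccl8 at 4.05 and Tpm3-rs7 at -3.08, and no gene shown changes side.

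Immune gene lists rose as groups in the libraries labelled GABP-OE, where a rise of Gabpa itself was not established. Of 16 measured immune cell markers 7 rose and 9 did not pass, 13 were higher when adjusted over the list alone (10 after median of ratios), and the list median lay 1.16 above that of all genes (camera adjusted p = 2.5e-09, adjusted p = 0.034 with an estimated correlation). Cd74, the class II invariant chain, rose from 29.9 ± 8.08 to 186 ± 76.7 FPKM, the complement gene C1qc from 3.15 ± 0.444 to 16.9 ± 5.88 and the T cell receptor gene Cd3g from 0.144 ± 0.0171 to 1.52 ± 0.682. Of 16 inflammatory mediators 5 rose and 11 were higher when adjusted over the list alone (8 after median of ratios, camera adjusted p = 5.97e-09, adjusted p = 0.034 with an estimated correlation). The chemokine genes Cxcl9, Ccl5, Cxcl10 and Ccl2 had log2 fold changes of 2.01, 2.30, 2.05 and 2.20 (limma adjusted p = 0.0075, 0.013, 0.014 and 0.038). Of 16 interferon response genes Isg15 and Cxcl10 rose and 12 were higher when adjusted over the list alone (1 after median of ratios, camera adjusted p = 9.24e-09, adjusted p = 0.034 with an estimated correlation). Across all comparisons these 3 lists, with GABP-OE, were the calls that held with an estimated correlation. After median of ratios the immune and inflammatory lists held again (0.032 each) and the interferon list had an adjusted p of 0.15, while C1qc, Cd3g, Cxcl9, Ccl5, Cxcl10, Ccl2 and Isg15 each lost the call and Cd74 kept it. By direction fry called the immune, inflammatory and interferon lists as deposited (adjusted p = 0.000503, 0.00174 and 0.000694), and extracellular matrix genes (0.0347).

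Some matrix and injury genes rose beside them. Of 24 extracellular matrix and fibrosis genes 4 rose, 20 did not pass and 13 were higher when adjusted over the list alone (0 after median of ratios, camera adjusted p = 2.45e-08, adjusted p = 0.36 with an estimated correlation). The called genes were Mmp2 (6.94 ± 0.521 against 1.66 ± 0.302 FPKM), Timp1 (3.91 ± 1.28 against 0.681 ± 0.171), Lox (5.62 ± 2.03 against 1.59 ± 0.951) and Col3a1 (31.1 ± 2.20 against 7.08 ± 5.21), which encode a matrix protease, its inhibitor, a collagen cross-linking enzyme and a fibrillar collagen. In the tubular injury list (12 measured) Havcr1, the kidney injury molecule gene, rose from 0.208 ± 0.154 to 2.81 ± 1.25 FPKM and Vcam1 from 1.24 ± 0.547 to 5.38 ± 0.937, the same 2 when adjusted over the list alone (0 after median of ratios, camera adjusted p = 0.0303, adjusted p = 0.47 with an estimated correlation). Adipose tissue genes were higher as well, with Cfd and Ucp1 called (Ucp1 1.86 ± 1.09 against 0.156 ± 0.215 FPKM), 3 of 7 when adjusted over the list alone (3 after median of ratios), camera adjusted p = 0.00381 and adjusted p = 0.44 with an estimated correlation. Each named gene of these 3 lists lost its call after median of ratios.

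Fatty acid oxidation, collecting duct, blood and mitochondrially encoded genes lay below the other genes with GABP-OE, with no member called. Of 23 PPAR-alpha targets and fatty acid oxidation genes 3 were above the all-gene median (camera adjusted p = 3.13e-08, adjusted p = 0.47 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase gene, was at 1.90 ± 1.46 against 37.8 ± 45.2 FPKM (limma adjusted p = 0.086), Acot1 at 1.86 ± 0.630 against 7.36 ± 4.40 and the fatty acid carrier gene Cd36 at 26.5 ± 4.83 against 14.1 ± 9.51. Red blood cell genes were low (7 of 8 negative, camera adjusted p = 3.05e-08, adjusted p = 0.18 with an estimated correlation). Hbb-bt was at 30.3 ± 30.5 against 57.8 ± 18.1 FPKM, Hbb-bs at 185 ± 192 against 301 ± 125 and Alas2 at 0.908 ± 0.601 against 2.32 ± 0.909. Collecting duct markers had camera adjusted p = 8.7e-05 (adjusted p = 0.37 with an estimated correlation), with the water channel gene Aqp3 at 4.87 ± 4.39 against 8.57 ± 8.46 FPKM and Slc4a1 at 2.74 ± 1.36 against 1.63 ± 0.471, Aqp2 at 50.2 ± 17.1 against 85.2 ± 77.3 and Atp6v1g3 at 9.26 ± 1.64 against 14.8 ± 9.40. Mitochondrially encoded genes had camera adjusted p = 3.05e-08 (adjusted p = 0.34 with an estimated correlation), with mt-Co3 at 1503 ± 588 against 1886 ± 709 FPKM and mt-Nd4l at 25.4 ± 11.8 against 35.5 ± 7.24, mt-Atp8 at 1.72 ± 2.01 against 3.23 ± 4.68 and mt-Cytb at 105600 ± 3686 against 131000 ± 14220. That list is not independent of the mitochondrial share of fragments (exact permutation p = 0.1). No member of these 4 lists passed when adjusted over the list alone, and after median of ratios 2 PPAR-alpha targets and 1 red blood cell gene were lower. Of the 10 list calls with GABP-OE, that of tubular injury was lost without db/m-veh 1 (camera adjusted p = 0.239) or db/m-GABP-OE 3 (0.165) and that of collecting duct markers without db/m-veh 3 (0.0597). In lists not called as groups, the lipid gene Scd1 rose from 1.43 ± 0.345 to 9.03 ± 2.30 FPKM (4 of 17 higher when adjusted over the list alone and 1 after median of ratios, camera adjusted p = 0.0801) and the proliferation marker Mki67 from 0.198 ± 0.094 to 1.10 ± 0.124 (1 of 15, 0.556). Slc22a7 rose from 13.9 ± 10.7 to 56.1 ± 16.1 (1 of 15 proximal tubule markers, 0.336) and Cyp7b1 from 6.47 ± 2.22 to 29.4 ± 18.2 (1 of 17 drug metabolism genes, 0.0933). Scd1, Mki67, Slc22a7 and Cyp7b1 all lost the call over all genes after median of ratios.

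In the libraries labelled GABP-KD, where Gabpa was not lower, tubular injury genes stood high and thick ascending limb genes low against db/db-veh, and no gene passed the test. Havcr1 was at 5.41 ± 3.12 against 0.568 ± 0.876 FPKM (SD, n = 3, log2 fold change 2.59, SE 0.51, limma adjusted p = 0.19) and Spp1, osteopontin, at 1331 ± 1775 against 267 ± 347, with Lcn2 at 15.9 ± 19.3 against 5.11 ± 8.39 and Clu at 24.1 ± 21.7 against 5.47 ± 4.18. All 12 tubular injury genes lay above the all-gene median, 4 were higher when adjusted over the list alone (1 after median of ratios), and the list had camera adjusted p = 0.000467 (adjusted p = 0.28 with an estimated correlation, 0.0715 without db/db-veh 1). Slc12a1, the salt transporter of the thick ascending limb, was at 15.6 ± 5.01 against 55.2 ± 31.3 FPKM and Egf at 5.06 ± 1.08 against 10.6 ± 5.40, Ptger3 at 1.32 ± 0.769 against 2.13 ± 1.42 and Kcnj1 at 5.72 ± 2.89 against 7.20 ± 3.16. All 7 thick ascending limb markers lay below the all-gene median (camera adjusted p = 9.26e-07, adjusted p = 0.28 with an estimated correlation), 1 being lower when adjusted over the list alone (2 after median of ratios). limma called 0 genes at an adjusted p under 0.05 (lowest 0.15), with 1839 at an unadjusted p under 0.05. After median of ratios it called 5, all lower, and voom called 4, or 6 with median of ratios sizes. The 5 genes, named after their values were seen, were Slc12a1 (log2 fold change -2.29 after median of ratios, adjusted p = 0.023), Slc22a30 (-3.08, 0.01), Kcnt1 (-2.38, 0.019), Mpped1 (-1.85, 0.041) and Gm6614 (-2.75, 0.01). Without db/db-GABP-KD 1 limma called 4 genes, and without db/db-veh 3 it called 1.

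Other lists called between the libraries labelled GABP-KD and db/db-veh held a mixture of tissue and stress genes, and several rested on single libraries. Red blood cell genes were low, with Hbb-bt at 5.37 ± 5.91 against 19.6 ± 9.32 FPKM, Hbb-bs at 50.5 ± 68.6 against 89.6 ± 41.6, Hba-a1 at 56.7 ± 52.1 against 143 ± 63.2, Hba-a2 at 3.81 ± 3.03 against 9.63 ± 4.12 and 5 of 8 lower when adjusted over the list alone (6 after median of ratios, camera adjusted p = 2.85e-10, adjusted p = 0.28 with an estimated correlation). Adipose tissue genes were low (2 lower over the list alone after median of ratios, camera adjusted p = 3.25e-05, adjusted p = 0.28 with an estimated correlation). Car3 was at 0.862 ± 0.322 against 5.35 ± 6.62 FPKM and Cfd at 0.253 ± 0.438 against 3.87 ± 6.21, Adipoq at 0.169 ± 0.223 against 1.18 ± 1.48 and Lipe at 2.92 ± 1.37 against 2.37 ± 1.39. Unfolded protein response genes were high, 12 of 14 above the all-gene median and 5 higher when adjusted over the list alone (0 after median of ratios, camera adjusted p = 0.00669, adjusted p = 0.46 with an estimated correlation). The chaperone gene Hspa5 was at 54.6 ± 4.87 against 21.4 ± 8.32 FPKM and Atf3 at 10.6 ± 15.2 against 1.30 ± 1.97, Atf4 at 66.8 ± 77.4 against 17.1 ± 5.72 and Xbp1 at 22.6 ± 17.0 against 8.03 ± 4.35. Inflammatory mediators were high with 6 higher when adjusted over the list alone (3 after median of ratios, camera adjusted p = 0.0161, adjusted p = 0.46 with an estimated correlation), the complement gene C3 being at 27.6 ± 17.7 against 7.08 ± 5.86 FPKM and Ccl5 at 2.37 ± 1.44 against 0.328 ± 0.340, Cxcl1 at 8.38 ± 6.52 against 3.36 ± 4.91 and Ccl2 at 2.48 ± 2.54 against 0.282 ± 0.147. Nuclear-encoded respiratory chain genes were high (24 of 27 above the all-gene median, list median 0.10 after median of ratios, camera adjusted p = 0.00446, adjusted p = 0.81 with an estimated correlation). Cox6a1 was at 274 ± 325 against 69.3 ± 52.7 and Cox5b at 61.9 ± 44.5 against 27.0 ± 24.3 FPKM, Cox6b1 at 143 ± 83.5 against 59.1 ± 38.4 and Cox4i1 at 116 ± 127 against 32.9 ± 12.6. Mitochondrially encoded genes were low (camera adjusted p = 1.56e-08, adjusted p = 0.29 with an estimated correlation), with mt-Co2 at 2125 ± 725 against 3052 ± 453 and mt-Nd4l at 40.6 ± 11.4 against 25.7 ± 7.83, mt-Atp6 at 1060 ± 454 against 1623 ± 949 and mt-Nd6 at 15570 ± 4219 against 20230 ± 4794. That list is not independent of the mitochondrial share of fragments (exact permutation p = 0.3). In db/db-GABP-KD 1 Cox6a1 was at 649.3 FPKM, against 70.04 and 102.5 in the other libraries of its group, and without that library the respiratory chain (camera adjusted p = 0.289) and mitochondrially encoded lists (0.0614) were not called. Without db/db-veh 1 the unfolded protein response (0.084) and inflammatory calls (0.428) were lost, and without db/db-GABP-KD 2 the inflammatory call (0.594). Of the 12 list calls of this comparison, 8 stayed without db/db-GABP-KD 1 or db/db-veh 1, 9 without db/db-veh 3, 10 without db/db-GABP-KD 2 or db/db-GABP-KD 3 and 12 without db/db-veh 2. By direction fry called immune cell, inflammatory, interferon, tubular injury and unfolded protein response genes, all higher (adjusted p = 0.0381 each). These fry results take in the all-gene shift.

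Further lists called in the same comparison were distal convoluted tubule, proximal tubule, drug metabolism and liver genes, each lower than other genes. Their camera adjusted p were 0.0161, 0.0321, 0.0102 and 0.0481, with adjusted p = 0.56, 0.81, 0.74 and 0.61 with an estimated correlation, and no member passed when adjusted over the list alone, while after median of ratios 3 drug metabolism genes were lower. Trpm6 and Wnk4 were at 5.21 ± 5.39 against 2.01 ± 0.418 and 24.6 ± 3.45 against 35.8 ± 17.2 FPKM, Slc12a3 and Calb1 at 19.8 ± 3.55 against 23.9 ± 8.49 and 17.4 ± 3.07 against 14.96 ± 3.41. The proximal tubule genes Slc7a13 and Slc4a4 were at 3.50 ± 3.02 against 10.98 ± 3.21 and 12.4 ± 11.6 against 5.79 ± 3.64, Slc13a3 and Slc22a7 at 23.4 ± 4.46 against 16.3 ± 8.51 and 0.469 ± 0.336 against 0.111 ± 0.0858. Vitamin D enzyme genes Cyp27b1 and Cyp24a1 were at 9.75 ± 11.6 against 2.88 ± 2.39 and 14.7 ± 0.711 against 6.88 ± 1.53, and the liver genes Fga and Ttr at 13.3 ± 17.3 against 4.01 ± 5.40 and 0.212 ± 0.0242 against 0.846 ± 0.992. Ugt2b38 and Cyp2j13 were at 13.8 ± 4.68 against 26.5 ± 4.70 and 0.530 ± 0.145 against 1.53 ± 0.791, and Fgb and Apoa2 at 0.696 ± 0.553 against 0.319 ± 0.552 and 2.00 ± 2.02 against 2.55 ± 1.59. The mean and the median of the distal convoluted tubule list differed in sign (0.02 and -0.11), as did those of the liver list (0.13 and -0.19), and the liver call was lost after median of ratios (adjusted p = 0.329). The liver call was also lost without db/db-veh 3, db/db-GABP-KD 2 or db/db-GABP-KD 3 (0.875, 0.133 and 0.165), the proximal tubule call without db/db-veh 1, db/db-veh 3 or db/db-GABP-KD 1 (0.0613, 0.285 and 0.603), the drug metabolism call without db/db-veh 3 or db/db-GABP-KD 3 (0.132 and 0.0568) and the distal convoluted tubule call without db/db-GABP-KD 1 (0.167).

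**Figure D4:**
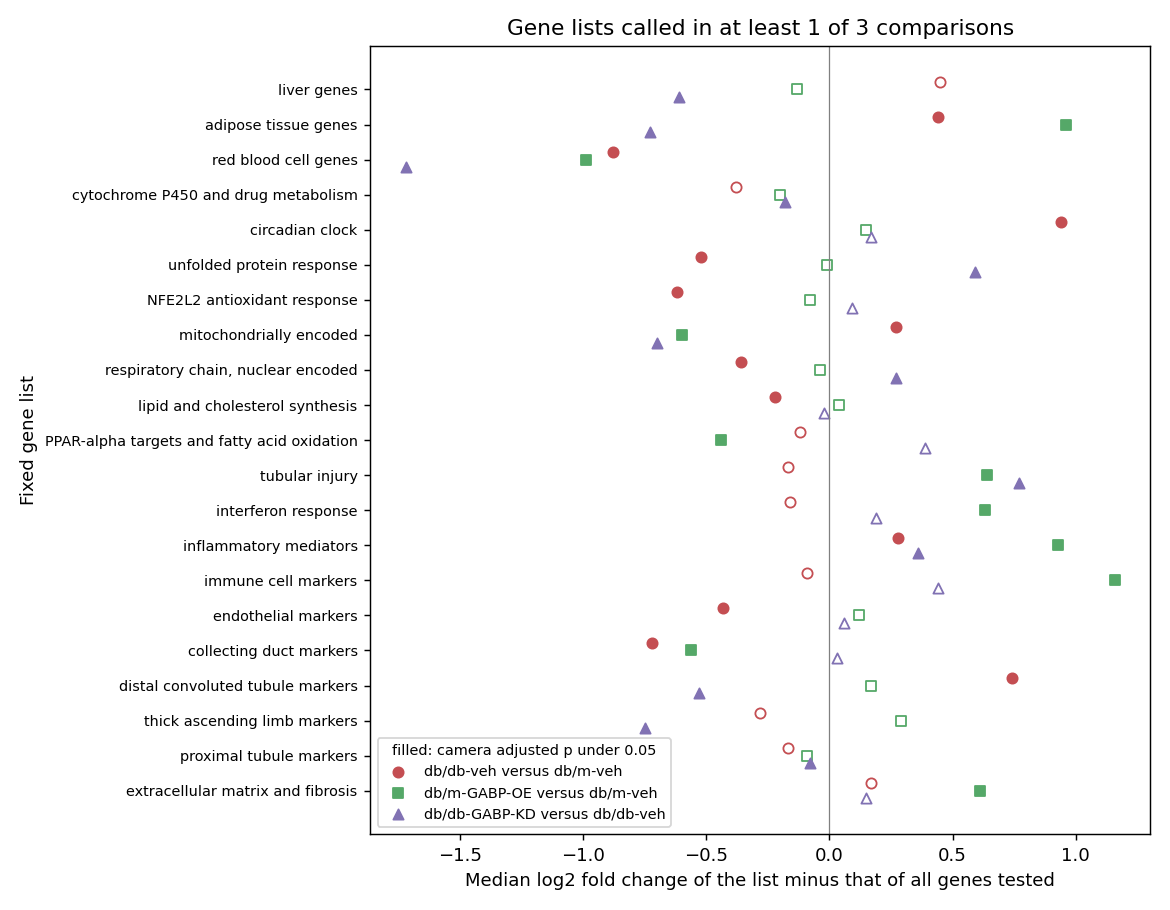
Median log2 fold change of each fixed gene list minus that of all genes tested (x axis) for 3 comparisons, filled where camera with its preset correlation had an adjusted p under 0.05. Immune cell markers lie at 1.16 with GABP-OE, and red blood cell genes at -0.88, -0.99 and -1.72 in the 3 comparisons.

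Genes called in more than 1 comparison were compared next, which bears on whether changes of the diabetic kidney shared genes with those of GABP-OE. Akr1c18, Cyp7b1, H2-DMb1 and Slc22a7 fell in db/db-veh and rose with GABP-OE, by 2.01, 1.99, 2.41 and 2.18. Independent lists would share 0.15 genes in opposite and 0.08 in the same direction. Both comparisons use db/m-veh, and after median of ratios H2-DMb1 was the 1 gene left in opposite directions, beside 1 in the same (Cnbd2, named after its values were seen). Summed over all pairs of these comparisons, with GABP-KD included and whatever the direction, the overlap was 0 without db/m-veh 2 and 13 without db/db-GABP-KD 1. Across genes, which are not independent replicates, these fold changes correlated at 0.10, while 100 simulations with no effect and shared controls gave 0.50 (covariance 0.02 against 0.08). Between db/db-veh versus db/m-veh and GABP-KD versus db/db-veh the correlation was -0.40, against -0.50 in simulations (covariance -0.08 and -0.08). With 3 control libraries no split into parts of at least 2 could be made. In the pair with GABP-KD the shared libraries alone gave as large a covariance, so this correlation shows no reversal beyond the sharing. After median of ratios Gm6614 and Kcnt1 were called in opposite directions in that pair (2 genes, of 22 and 5 called). They were named after their values were seen, and the shared db/db-veh libraries favour opposite directions. In the pair with GABP-OE sharing favours changes in the same direction, not in opposite ones.

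GABP-OE and GABP-KD effects were then set against each other, in comparisons that share no library. Across genes their fold changes had a Pearson correlation of 0.027 (exact permutation p = 0.91 over 100 splits) and a Spearman correlation of 0.042 (exact permutation p = 0.87). limma called 17 genes with different effects, 11 with a more positive effect of GABP-OE and 6 with a more negative one, and 702 at an unadjusted p under 0.05. Ccl8 (difference 3.90, SE 0.53, limma adjusted p = 0.008) and Retnla (3.39, SE 0.43, limma adjusted p = 0.0064) were among the former, and Tpm3-rs7 (-4.01, SE 0.64, limma adjusted p = 0.02) among the latter. Strain and the intended direction of GABP go together in this contrast. Gabpa was not lower in the libraries labelled GABP-KD, and its rise in those labelled GABP-OE was not called. After median of ratios 10 genes were called, 7 and 3 by direction, and voom called 1. The count was 40 without db/m-veh 1, 7 without db/m-veh 2, 1 without db/m-veh 3, 4 without db/db-veh 1, 9 without db/db-veh 3, 11 without db/m-GABP-OE 1, 5 without db/m-GABP-OE 2, 6 without db/m-GABP-OE 3 and 11 without db/db-GABP-KD 2.

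Lists that differed by camera between the 2 effects numbered 11 of 32, with no member called and none called with an estimated correlation. With fry no list was called, by direction (lowest adjusted p = 0.391) or with members free to move either way (lowest 0.332). Each value that follows is a log2 difference, GABP-OE effect minus GABP-KD effect, with Gabpa not lower in the libraries labelled GABP-KD. Adipose tissue genes were more positive (camera adjusted p = 2.3e-06, adjusted p = 0.29 with an estimated correlation, 4 of 7 higher when adjusted over the list alone, as after median of ratios). Cfd was at 4.85, Car3 at 2.99, Adipoq at 2.37 and Ucp1 at 1.48. Thick ascending limb markers had camera adjusted p = 0.00013 (adjusted p = 0.46 with an estimated correlation, 1 higher over the list alone and 2 after median of ratios). Slc12a1 was at 2.67, Egf at 1.55, Umod at 1.36 and Ptger3 at 1.18. Immune cell markers had 0.00013 (0.29, 3 higher over the list alone and 4 after median of ratios). Lyz2 was at 2.00, Csf1r at 1.97, Cd3g at 1.85 and the neutrophil gene S100a8 at -1.87. Matrix genes had 0.00135 (0.79, 1 higher over the list alone, as after median of ratios). Postn was at 2.14, Col3a1 at 2.11, Mmp2 at 1.32 and Col1a1 at 1.15. Interferon response genes had 0.00554 (0.46). Cxcl10 was at 1.37, Rsad2 at 1.12, Ifit1 at 1.07 and Oas1a at 0.97. Inflammatory mediators had 0.00893 (0.51). Il18 was at 1.59, Cxcl9 at 1.28 and Vcam1 at 0.86.

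More negative with GABP-OE than with GABP-KD were genes of fatty acid oxidation, protein folding stress, respiration, collecting duct and podocytes. PPAR-alpha targets had camera adjusted p = 9.61e-05 (adjusted p = 0.79 with an estimated correlation, 1 lower when adjusted over the list alone, as after median of ratios). Cyp4a14 was at -5.68, Acot1 at -2.58 and the lipid droplet gene Plin2 at -2.03. Unfolded protein response genes had 0.00731 (0.51). Hspa5 was at -1.07, Atf4 at -0.93, Ddit3 at -0.91 and Asns at -0.78. Nuclear-encoded respiratory chain genes had 0.00893 (0.86). Cox5a was at -1.22, Cox7a2 at -0.96 and Ndufa4 at -0.71. Collecting duct markers had 0.00921 (0.79). Aqp2 was at -1.44, Atp6v1g3 at -1.29, Atp6v0d2 at -1.06 and Scnn1b at -0.81. Podocyte markers had 0.0426 (0.84). Wt1 was at -1.14, Podxl at -0.83 and Dpp4 at -0.67. All 11 lists stayed called after median of ratios. Between 7 (without db/db-GABP-KD 1) and 10 of the 11 stayed with 1 library left out, and of the 12 leave-outs 8 ended the podocyte call, 4 each the matrix and collecting duct calls, 3 each the inflammatory and respiratory chain calls, 2 the unfolded protein response call and 1 the interferon call. Without db/db-GABP-KD 1 the matrix (camera adjusted p = 0.781), respiratory chain (0.404), interferon (0.131) and inflammatory calls (0.0569) were lost. The adipose, thick ascending limb, immune and PPAR-alpha calls stayed in all 12.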

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

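Tests of the patterns here were chosen after the results were seen, except that of lymphoid markers, whose prediction was written before the values of those genes were looked at. Effects of GABP-OE and GABP-KD differed for 17 genes by the contrast of the 2 effects, and this difference drew attention to the genes that follow. More positive with GABP-OE were Ccl8 (3.90), Igfbp2 (3.42), Clec3b (3.41), Retnla (3.39), Kcnt1 (3.38), Mgl2 (2.85), Coch (2.81), Mpped1 (2.69), Ear2 (2.65) and Cd4 (1.88), all as log2 differences. More negative were Tpm3-rs7 (-4.01), Fam25c (-3.77), Tm4sf5 (-3.14) and Pianp (-2.93). Igfbp2, Clec3b, Coch, Ear2, Cd4, Tm4sf5 and Pianp lost the call after median of ratios, and 1 of the 14, Retnla, kept it without db/m-veh 3. Mgl2 and Cd4, genes of macrophages and T helper cells, stood at 4.26 ± 0.448 and 1.65 ± 0.538 FPKM (SD, n = 3) in db/m-GABP-OE and below 0.32 in the other 3 groups, and their difference was called in 21 and 6 of 22 alternatives. Tpm3-rs7 stood at 30.3 ± 15.6 in db/db-GABP-KD and 14.8 ± 3.85 in db/db-veh. In 5 of 100 splits drawn within the db/m and the db/db libraries, the real one included, at least 17 genes were called, and another split called 95, so chance cannot be excluded for this count and the libraries hold structure besides their groups.

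Nearly all of the 245 genes called with GABP-OE were higher, in libraries with a lower mitochondrial share. If that share alone had raised every nuclear FPKM, no gene would be called higher after median of ratios, and 21 were. Of the 217 other genes called higher, whose median log2 fold change went from 1.47 to 1.14 at a nearly equal standard error (0.31 and 0.32), 49 still had a p within the largest one called before scaling (0.000949) and lost the call to a stricter adjustment, while the others had a larger p. These 217 were picked for large rises in the same data. Their median thus had to stay above 0 once the all-gene shift was removed, and it decides nothing about the share. For the 21 genes the share does not account for the whole of the change, though it may add to it. A change in the tissue with GABP-OE stays open, untested. Of the 10 splits of the 6 libraries the real one called 245 genes and the highest other 0, and 10 splits are too few for a share under 0.05.

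Immune cell genes were higher with GABP-OE, and the mitochondrial share as the whole cause is argued against by their mean log2 fold change after median of ratios, 1.26 (95% interval 0.63 to 1.89). More retained blood would raise the globin genes as much, and their mean was -1.28 (95% interval -2.78 to 0.22), below the interval of the immune genes, which argues against it as the cause. Lymphoid tissue dissected with the kidneys may contribute, since 12 lymphoid markers, of which 5 were testable and 3 also stand in a fixed list, summed to 3.31 times the db/m-veh level with no overlap (exact permutation p = 0.1). Most of that sum was Ccl21a (37.6 ± 1.67 against 6.88 ± 2.14 FPKM) and Ccl19 (5.32 ± 2.19 against 1.21 ± 1.14), with Cd79a at 2.76 ± 1.29 against 0.691 ± 0.447, whereas Cd79b was 0.391 ± 0.438 against 0.455 ± 0.399 and Glycam1 was listed at 0. Adipose tissue genes were higher in the same libraries (list median 1.34, 7 of 7 positive, 3 higher over the list alone, as after median of ratios), so fat dissected with the kidneys stays open, as do immune cells within the kidney of mice labelled GABP-OE, untested. After median of ratios immune cell markers also lay higher in the libraries labelled GABP-KD (camera adjusted p = 0.00209, 0.27 with an estimated correlation). As deposited that list had camera adjusted p = 0.237 there, and fry, which takes in the all-gene shift, gave adjusted p = 0.0381. The control was labelled vehicle and the way GABP was raised is not given. An effect of that way therefore cannot be told apart from one of GABP.

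Gabpa was not lower in the libraries labelled GABP-KD. A fall hidden by the lower mitochondrial share was looked for after median of ratios, with a log2 fold change of -0.5 as cut-off, set after the values were seen. The lower 95% bound was -0.24, which argues against a fall of that size. A smaller fall is not excluded. Without db/db-GABP-KD 1, the library with the highest Gabpa as deposited, the bound after median of ratios was -0.35. That library alone therefore does not hide a fall to -0.5, while a smaller one is again not excluded. An exchange of libraries between db/m-GABP-OE and db/db-GABP-KD is argued against by Ugt1a2, at 9.85 FPKM or more in every db/db-GABP-KD library and at most 0.1 in db/m-GABP-OE, and by Slc22a7, at most 0.832 against at least 38.8. An exchange within the db/db groups, or lower GABP protein with unchanged RNA, stays open, with Gli1 at 0.044 ± 0.036 FPKM in db/db-GABP-KD and 0.492 ± 0.41 in db/db-veh (exact permutation p = 0.2).

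For the libraries labelled GABP-KD against db/db-veh, the real split called 0 genes. All 10 splits then call at least as many whatever the data, so their share cannot decide anything. The highest other was 20, in the split that put db/db-GABP-KD 1 with db/db-veh 1 and db/db-veh 3. Another split called 11 and the remaining ones 0. Calls in these splits may reflect a structure of these 6 libraries other than the groups, which was not tested. For db/db-veh against db/m-veh the real split called 12 genes and the highest other 0, with 1 of 10 splits as large. Here too 10 splits are too few for a share under 0.05, as they are for GABP-OE (1 of 10).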

How the results depend on the processing

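Tests on voom, on median of ratios without db/db-GABP-KD 1 and on the leave-out of that library outside its own comparisons were chosen after the data were seen, the others before. None of the called genes named by the rule changed direction, and the alternatives were not run for 2210011C24Rik, Gm6614, Kcnt1 and Cnbd2 in the comparison of vehicle groups. Of 170 alternative values for the 10 called genes between the vehicle groups 123 stayed past the threshold, of 625 for 37 genes with GABP-OE 431 did, and of 308 for 14 genes in the difference of effects 182 did. Counts are given in the order vehicle groups, GABP-OE, GABP-KD and difference, and the cause of a change was not tested unless named. With no filter they were 2, 256, 1 and 7; median of ratios, 22, 27, 5 and 10; quantile normalization, 26, 33, 11 and 11; library weights, 642, 2757, 158 and 376. No variance trend gave 123 for GABP-OE and 6 for the difference, pseudocount 0.1 gave 62 for GABP-OE, and a filter of FPKM 1, which tests fewer genes, 159. Fits of the 2 groups alone gave 19 and 590 for the first pair. voom gave 3, 7, 4 and 1, with median of ratios sizes 1, 3, 6 and 1, and median of ratios without db/db-GABP-KD 1 gave 52, 77 and 11 for the first 3. Leaving out libraries gave 2 to 48, 39 to 559, 0 to 4 and 1 to 40. An equal FPKM sum, pseudocount 1 and a minimum log2 fold change of 1 kept each of the 4 counts within 1.5 times.

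Replicate numbers did not pair the libraries, since deviations from group means correlated at -0.48 to 0.38 over 18 pairs, 5 of them over 0.1 and 7 of them the best match to the own number. With the number as a block the counts were 13, 277, 0 and 11. The overlap of calls, summed over the pairs of comparisons whatever the direction, was 1 with pseudocount 0.1, 9 with quantile normalization and 0 to 13 across leave-outs. The correlation of GABP-OE and GABP-KD fold changes turned to -0.025 with pseudocount 0.1 and -0.006 with the filter of FPKM 1, and ran from -0.081 to 0.16 across leave-outs. List calls with an estimated correlation were 0, 3, 0 and 0, and for the vehicle groups 7 with median of ratios and 7 with quantile normalization. Median of ratios gave 13 with GABP-OE, adding glucose handling (camera adjusted p = 0.0364), mitochondrial genome expression factors (0.0241) and the NFE2L2 response (0.0315), all lower. It gave 14 with GABP-KD, adding epithelial adhesion (0.0338, higher), immune cell markers (0.00209, higher) and mitochondrial genome expression factors (0.0282, lower), and 12 for the difference, adding distal convoluted tubule markers (0.0305, higher).

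Values that turned were all of genes not called. Between the vehicle groups Gabpa became 0.20 with median of ratios and 0.17 with quantile normalization, Gabpb2 0.02 and 0.01, and mt-Nd4l 0.24 with quantile normalization. Library weights gave mt-Atp8 0.89 with GABP-OE, Plin2 0.07 in the difference and, with GABP-KD, Gabpb1 -0.14, Slc4a4 -0.16, mt-Atp6 0.06, Cyp27b1 -0.11, Lipe -0.21, Fga -0.12 and Fgb -0.04. With GABP-KD median of ratios gave Calb1 -0.37 and Lipe -0.15, and quantile normalization Slc13a3 -0.01, Calb1 -0.50, mt-Nd4l -0.11 and Lipe -0.15. Leave-out ranges that crossed 0 were, between the vehicle groups, -0.11 to 0.29 (Gabpb1), -0.36 to 0.01 (Gabpb2), -0.96 to 0.80 (mt-Atp8) and -0.39 to 1.87 (Cfd); with GABP-OE, -1.38 to 0.24 (Aqp3), -0.83 to 0.25 (Aqp2), -0.69 to 0.04 (mt-Co3) and -1.01 to 0.74 (mt-Atp8); with GABP-KD, -0.03 to 0.80 (Gabpb1), -0.47 to 0.04 (Slc12a3), -0.17 to 0.63 (Lipe) and -1.13 to 0.22 (Apoa2). For the difference they were -0.52 to 0.07 (Gabpa), -0.18 to 0.64 (Gabpb1), -0.30 to 0.08 (Gabpb2), -3.15 to 0.12 (Plin2), -1.21 to 0.13 (Ndufa4) and -1.43 to 0.01 (Atf4). Depth limits genes with few fragments most, since 1 fragment of Gli1 is worth 0.0206 to 0.0295 FPKM.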

Other observations

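Tests of sex-linked genes and Ptch1 here were chosen after the values of the main comparisons were seen, and the test of androgen-dependent genes was written before their values were looked at. Ptch1, a receptor gene known to be induced by GLI factors, was at 0.581 ± 0.231 FPKM (SD, n = 3) in db/m-GABP-OE and 0.423 ± 0.102 in db/m-veh (log2 fold change 0.21, limma adjusted p = 0.68). Y-linked Ddx3y was at 5.42 ± 0.907 FPKM in db/m-veh, 4.80 ± 1.15 in db/db-veh, 8.77 ± 2.33 in db/m-GABP-OE and 9.59 ± 7.04 in db/db-GABP-KD.

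Kap and Cyp7b1, which need androgen in mouse kidney, fell in db/db-veh, and a hypothesis is that androgen action was lower in these kidneys. It predicted that 7 other androgen-dependent genes would lie lower, and their median log2 fold change after median of ratios was -0.89, with 7 of 7 lower and their mean log2 level at 2.63 to 2.96 in db/db-veh libraries against 3.17 to 4.74 in db/m-veh. The summed level of the same 7 genes was 110 ± 20.6 against 259 ± 149 with overlapping libraries (exact permutation p = 0.2). No single one was called, and 4 of the 7 also stand in a fixed list. Cyp4a12a was at 4.92 ± 5.93 against 54.6 ± 56.6 FPKM and Odc1 at 10.5 ± 2.61 against 23.6 ± 6.42. Genes higher in females, Prlr and Slc7a12, had a median of 0.67, but their summed level overlapped between the groups (ratio 1.46, exact permutation p = 0.5). With GABP-OE the mean log2 level of the 7 genes was 4.16 to 4.45, within the range of db/m-veh. After median of ratios 5 of the 7 were higher there and 2 lower. The summed level of Prlr and Slc7a12 was 0.191 times that of db/m-veh, with no overlap (exact permutation p = 0.1). Genes of this kind thus varied within the db/m strain too. The values of the vehicle groups may reflect lower androgen action in db/db-veh, which these data cannot separate from other effects of the db/db genotype.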
